A study of Mus musculus with 3 samples.

How the data were processed

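Droplet single-cell RNA sequencing libraries of pooled mouse hearts were analysed, 1 library of 3 pooled hearts for each of 3 groups. Per the labels, hearts were enzymatically digested and captured with 10x Genomics 3′ chemistry, and the submitters' processing notes name Cell Ranger, Seurat and the genome build mm10. Tool versions, the gene annotation and any filter on cells are not given in the sources used here. The deposited matrices hold counts, whole numbers of UMIs per gene and cell, with 1 matrix per library. As deposited, no cell had 30% or more of its UMIs from mitochondrially encoded genes and none had over 2499 genes. The 3 libraries use the same list of 30415 gene symbols, of which 29240 matched GENCODE M21, the annotation of GRCm38 used for positions.

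Groups were taken from the sample titles. The treatment tags give the opposite antibody for the libraries titled PD1/PEM and PDL1/ATZ, and no value in the data was used to settle this. With 1 library per group no test, standard error or p-value was computed. The comparisons, cell filters, class markers, 29 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

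Doublets were scored per library over all deposited cells, against simulated doublets with 50 neighbours, and the top-scoring cells were marked at 0.8% per 1000 cells, which were 724 isotype, 326 PD1/PEM and 1076 PDL1/ATZ cells, including some over the mitochondrial limit. Unmarked cells with at least 200 genes and at most 25% mitochondrial UMIs were kept: 2602, 1981 and 11590 cells met that limit and 2241, 1811 and 10514 were left without the marked ones. The retained cells held 3965388, 4100197 and 12460191 UMIs. Counts were scaled to 10000 per cell and log transformed, and the 2000 most variable genes, chosen within libraries, gave 30 principal components. A graph of 15 nearest neighbours was clustered jointly, without batch correction, by the Leiden algorithm at resolution 1 with random seed 1. A class needed at least 3 markers with 10 or more UMIs and a 2-fold ratio over other cells. A cluster whose 10 leading genes held more markers of another type stayed unnamed, as did a cluster with few UMIs for its libraries and no marker among its leading genes. Ratios for naming were taken within libraries, and a cluster with as many markers of a second type was left unnamed. These last 2 rules were set after the clusters had been seen.

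UMIs were summed over the cells of a class and scaled to CPM by the UMI total of these cells. Sums have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95% and all for counting error only. Log2 ratios use a pseudocount of 0.5, and genes needed 50 UMIs over the 2 libraries compared. A gene was counted as apart when its ratio was at least 2-fold and its interval excluded no difference. A count of 0 was set at 3 counts for bounds. Values given as at least or up to rest on this rule, and the 95% intervals reach further. For a gene list the median log2 ratio was ranked among 10000 random lists of the same size matched in 20 bins of expression, for lists with at least 5 members. For the direct comparison of shallower and deeper cells, cells were thinned to 700 UMIs.

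Named genes were the 5 highest and 5 lowest per class, ranked by the interval bound nearest no difference among genes at least 1.5-fold apart whose level in the class was at least 0.1 of that in the highest class, in the 3 classes with the most cells in their smallest library. Up to 4 members of each described list, and Cd274 and Pdcd1, were also named. The value of 1 list member is not reported here. Sex-linked, haemoglobin and unnamed gene models were counted but not ranked. Symbols that are clone names were treated as unnamed models, a choice made after the data were seen. Comparisons over all retained cells, with 10 genes per direction, and of clusters 3, 5 and 6 by number were also added after the clusters were seen, since few cells fell into named classes. In comparisons with the PDL1/ATZ library, symbols with 0 UMIs over all deposited cells in 1 of the 2 sets of libraries (1942 read in the other libraries only, 2893 read in PDL1/ATZ only) were left out, a choice made after the difference had been seen. Of these, 162 pairs are older and newer symbols of the same gene. Lists of atrial and ventricular genes were added after Nppa, Nppb and Bmp10 had been seen in the data.

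The ratio and list steps were tested on Poisson counts drawn from the isotype profile, at the UMI totals of the cells under the mitochondrial limit. The draws hold no variation between cells, hearts or libraries, so they check counting only and do not estimate false calls in these data. A list of 20 genes raised 1.5-fold was at percentile 100.0 in both comparisons. Lists of 20 unaltered genes were at percentile 57.8 for PD1/PEM and 9.8 for PDL1/ATZ. For PD1/PEM against isotype, over 11094 genes, 95.8% of intervals held the true ratio, 98.9% of genes altered 3-fold and 4.2% of those altered 1.5-fold passed the 2-fold rule, and 14 unaltered genes passed. For PDL1/ATZ against isotype, over 13344 genes, these values were 95.5%, 100.0%, 2.1% and 43. Alternatives were other mitochondrial limits, gene minimums, UMI minimums, scalings, resolutions, clustering choices, doublet removal and thinning. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.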

Results

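Hearts of NOD/SCID mice, a strain that lacks functional T and B lymphocytes, were profiled by droplet single-cell RNA sequencing after treatment with pembrolizumab (an antibody against the receptor PD-1), atezolizumab (an antibody against its ligand PD-L1) or an isotype control antibody. Injections were given on days 0 and 7, and the hearts were taken on day 14. Each of the 3 groups is 1 pool of 3 hearts in 1 library, so there was no replicate, no test between groups was possible, and every interval below covers counting error only. The isotype library held 9510 cells and 16677883 UMIs (unique molecular identifiers, each standing for 1 captured transcript), the library titled PD1/PEM 6388 cells and 14766346 UMIs, and the library titled PDL1/ATZ 11599 cells and 15144668 UMIs. The labels conflict on the antibodies: the library titled PD1/PEM carries the treatment tag atezolizumab and the library titled PDL1/ATZ the tag pembrolizumab. The libraries are therefore called by their titles, and no difference below can be assigned to either antibody by name.

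Mitochondrially encoded transcripts set the libraries apart before any comparison of genes. They made up a median of 27.1% of the UMIs of a cell in the isotype library and 26.9% in the PD1/PEM library, against 8.05% in the PDL1/ATZ library. Cells with over 20% were 94.8%, 94.1% and 0.457% of the 3 libraries in the same order. A limit of 25% and removal of predicted doublets left 2241 isotype, 1811 PD1/PEM and 10514 PDL1/ATZ cells, with medians of 1527, 1778 and 959 UMIs and 886, 1027 and 721 genes per cell. After thinning each cell to 700 UMIs, which left out 125, 45 and 413 shallower cells, the median was 454, 456 and 547 genes. The isotype and PD1/PEM libraries shared 23 cell barcodes, and neither shared any with the PDL1/ATZ library. Between the isotype and PDL1/ATZ libraries, 161 gene symbols had at least 500 UMIs in 1 library and 0 in the other, against 0 such symbols between the isotype and PD1/PEM libraries.

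Fibroblast-like cells, the matrix-producing cells of the heart wall, made up 1.87% of retained isotype cells (95% Clopper-Pearson interval 1.35 to 2.52, 42 cells), 2.98% of PD1/PEM cells (2.25 to 3.87, 54 cells) and 3.27% of PDL1/ATZ cells (2.94 to 3.63, 344 cells). Macrophage-like cells were 0.268% (0.0983 to 0.582, 6 cells), 0.607% (0.304 to 1.08, 11 cells) and 1.38% (1.16 to 1.62, 145 cells) in the same order. Mesothelial-like cells, which line the outer surface of the heart, were 0.0892% (0.0108 to 0.322, 2 cells), 0.110% (0.0134 to 0.398, 2 cells) and 0.780% (0.621 to 0.967, 82 cells). The PD1/PEM and isotype intervals overlapped for all 3 classes. At a clustering resolution of 0.5 fibroblast-like shares were 1.12% in the isotype and 1.05% in the PD1/PEM library, the opposite order, and under 6 other settings no cluster could be given that name. With each library clustered alone, no isotype or PD1/PEM cluster met the marker rule for macrophage-like or mesothelial-like cells. Their shares of 0% there mean that no cluster was named, not that such cells were absent. Under a mitochondrial limit of 10% these shares were also 0%, with 14 isotype and 7 PD1/PEM cells left. The mesothelial-like share of PDL1/ATZ was 1.29% without doublet removal. No cluster met the marker rule for cardiomyocytes, endothelial cells or lymphocytes. Cluster 8, with markers of pericytes and the smooth muscle gene Lmod1 among its leading genes, stayed unnamed and held 0.848%, 0.828% and 2.91% of the cells.

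The other cells fell into clusters that followed the libraries. Cluster 3, led by the mitochondrial gene mt-Nd6 and the smooth muscle myosin gene Myh11, held 69.2% of isotype and 67.4% of PD1/PEM cells, and 1.67% of its cells came from the PDL1/ATZ library. Cluster 5, led by genes that include the adrenergic receptor Adra1a and the myosin Myh7b, held 15.4% and 12.8% of isotype and PD1/PEM cells. Cluster 6, whose leading genes include Fgf12 and the calcium release channel Ryr3, held 10.3% and 11.4%. Clusters 1, 2 and 4 drew 98.1%, 99.7% and 99.4% of their cells from the PDL1/ATZ library. Nppa and the atrial myosin light chain Myl7 led cluster 1, Lrrc4c and Kcnj3 were among the leading genes of cluster 2, and Rps6ka2 and Stox2 led cluster 4. These genes set the clusters apart only weakly. The highest fold of a leading gene over other cells of the same libraries was 1.71, 2.31 and 2.81 in clusters 1, 2 and 4. No marker of any cell type met the 2-fold rule in them, and cluster 1 had a median of 814 UMIs per cell. Cluster 4 had 0 of 2241 isotype cells, which allows a share of up to 0.134%. Cluster 11 had 29 cells, all from the PDL1/ATZ library. With 1 library per group, a cluster drawn mostly from 1 library cannot be read as a cell type present in that group.

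The first comparison asked how the hearts behind the PD1/PEM library differed from the isotype hearts. Bmp10, Nppb and Nppa were lower in the PD1/PEM library. Bmp10, an atrial growth factor, stood at 9.76 against 73.9 CPM (counts scaled to the UMI total of the cells summed), 7.49-fold lower (5.43 to 10.8), and Nppb, which encodes B-type natriuretic peptide, at 28.0 against 151 CPM, 5.38-fold lower (4.41 to 6.64). Nppa, the atrial natriuretic peptide gene, was 3.08-fold lower (2.98 to 3.20), at 1000 against 3090 CPM. Of the early growth response transcription factors, Egr3 was 5.29-fold higher (4.32 to 6.59), at 143 against 27.0 CPM, and Egr2 4.13-fold higher (2.81 to 6.39). On the mouse genome build GRCm38, Nppb (chromosome 4, 147985788 to 147987205) and Nppa (chromosome 4, 148000722 to 148002079) are neighbouring protein-coding genes, Bmp10 lies on chromosome 6 (87428994 to 87437677) and Egr3 on chromosome 14 (70077203 to 70082614).

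Among the other genes lowest in the PD1/PEM library were Flnc, the muscle filamin (3.06-fold lower, 2.77 to 3.40), Ppargc1a, a coactivator of mitochondrial biogenesis (2.46-fold lower, 2.36 to 2.56, at 877 against 2150 CPM), and Phka1, a subunit of phosphorylase kinase (2.81-fold lower, 2.44 to 3.25). Sox18, an endothelial transcription factor, was 3.22-fold lower (2.29 to 4.66), Fgfr3 2.79-fold, Tinagl1 2.58-fold and Ryr3 2.26-fold. The highest genes after Egr3 included Klhl38 (5.20-fold, 3.31 to 8.88), Hlx (4.13-fold), Slc24a2 (2.82-fold), Dach1 (2.53-fold) and the potassium channel gene Kcnj3 (2.44-fold). Spry4 and Errfi1, feedback inhibitors of growth factor receptor signalling, were 3.66-fold (2.93 to 4.63) and 2.71-fold (2.49 to 2.96) higher, and Apold1, an early response gene of endothelium, 3.05-fold (2.76 to 3.38). Of 10620 genes with at least 50 UMIs, 115 were at least 2-fold higher and 74 at least 2-fold lower with a counting interval that excluded no difference. These numbers follow the depth asked of a gene, with 261 and 185 at a minimum of 10 UMIs and 45 and 26 at 200, and were 1 and 3 under the 10% mitochondrial limit.

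**Figure D1:**
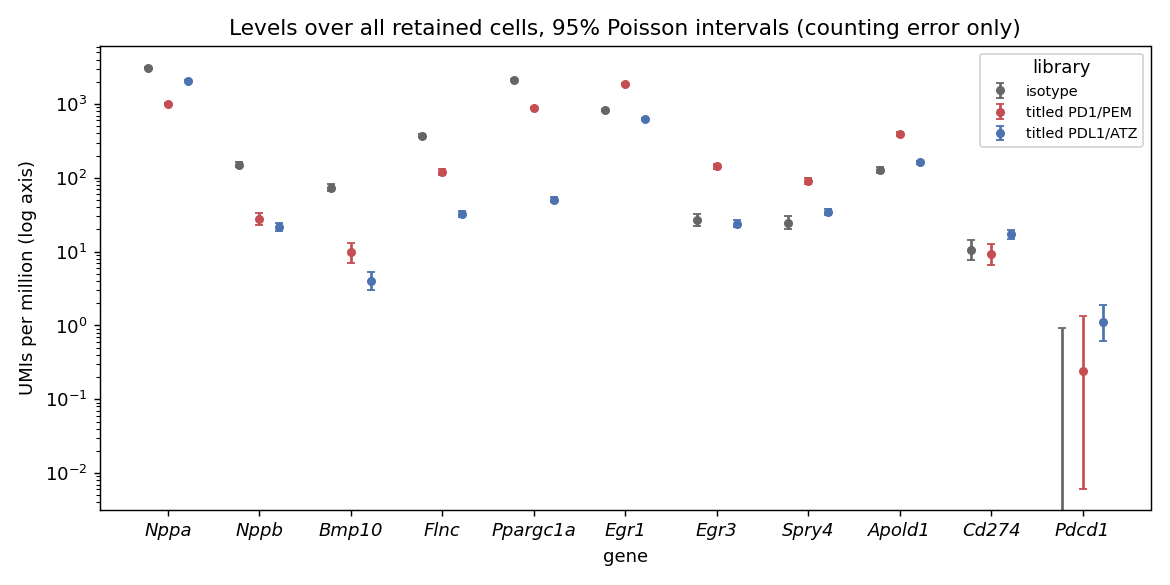
Levels of named genes over all retained cells, in CPM on a log axis, with 1 point per library and 95% Poisson intervals that cover counting error only. Nppa, Nppb and Bmp10 are highest in the isotype library, and Egr1, Egr3, Spry4 and Apold1 are highest in the library titled PD1/PEM.

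Gene lists of heart muscle lay lower in the PD1/PEM library as groups. All 20 measured sarcomere genes were lower (median log2 ratio -0.45), with Actc1, the cardiac actin, at -0.86, and the myosin light chains Myl7 at -0.85, Myl3 at -0.84 and Myl4 at -0.67. All 9 natriuretic and stress genes were lower (median -0.52), among them Xirp2 at -0.67 and Fhl1 at -0.55. Myh7 and Acta1 are in both this list and the sarcomere list, so the 2 are not independent. Of 50 nuclear genes of oxidative phosphorylation 49 were lower (median -0.45), such as Atp5g3 at -0.74 and Ndufa4 at -0.73, while the 13 genes of the mitochondrial genome split 7 to 6 around a median of 0.00. Glycolysis genes had 16 of 20 members lower (median -0.36), with the kinases Hk2 at -1.06 and Pfkp at -1.01 and the regulator Pfkfb3 at 0.71. Fatty acid genes had 20 of 28 lower (median -0.33), with Acadvl at -0.65. In the list of calcium handling and conduction 11 of 15 were lower (median -0.30), with Sln at -1.0 and Kcnj3 at 1.29. By at least 1.5-fold beyond counting error, 6 of the 20 sarcomere, 3 of the 9 natriuretic, 10 of the 50 nuclear oxidative phosphorylation, 4 of the 20 glycolysis, 5 of the 28 fatty acid and 3 of the 15 calcium handling genes were lower, and 1 glycolysis and 1 calcium handling gene higher. The median of each of these lists except that of the mitochondrial genome lay at or under the percentile 0.3 of 10000 random lists matched on expression. Beside them, all 10 transcripts taken as a sign of free cardiomyocyte RNA were lower (median -0.59), and the 4 haemoglobin genes were higher (median 0.87). Most of these 10 transcripts are also in the sarcomere list, so their drop is not a separate result. A sum over all retained cells also cannot tell free RNA from RNA of muscle cells. Across 10509 genes the ratio of PD1/PEM to isotype was also higher for genes with a longer genomic span (Spearman rho 0.184).

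Immediate early and type I interferon genes lay higher in the PD1/PEM library. Of 28 immediate early and heat shock genes, which respond to cell stress and to tissue digestion, 23 were higher (median 0.36, percentile 100), led by Egr2 at 2.05, Btg2 at 1.20, Egr1 at 1.17 and Nr4a1 at 1.15. Of 17 type I interferon response genes 14 were higher (median 0.41, percentile 100), with the ubiquitin-like Isg15 at 1.05, Rtp4 at 0.82, Ifi27l2a at 0.69 and Rsad2 at 0.62. The list of NF-kB and TNF response genes had 14 of 20 higher (median 0.29, percentile 99.9), with the chemokines Ccl7 at 1.51 and Cxcl2 at 0.96, Relb at 1.03, and the adhesion molecule Sele at -0.76. Immune checkpoint genes had 7 of 9 higher (median 0.34, percentile 98.7), with the costimulatory ligand Cd86 at 1.08. Cd86 was also a leading gene of the macrophage-like cluster, which held 12752 UMIs in the isotype and 35395 in the PD1/PEM library. For Cd86 a change of expression therefore cannot be told from a change in the mix of cells. Within cluster 3 alone 6 of 7 measured checkpoint genes were higher (median 0.45, percentile 99.5). Smaller lists of recruited macrophage genes (4 of 6 higher) and proliferation genes (5 of 7 higher, median 0.45) were at percentiles 99.8 and 99.4, with S100a4 at 0.89 and Stmn1 at 1.01. Only 6 of the 16 recruited macrophage genes and 7 of the 21 proliferation genes were measured. The 6 were Cxcl2, Thbs1, S100a4, S100a6, H2-Aa and Cd74, without Ccr2 or Ly6c2, and Cxcl2 is also in the NF-kB list. This percentile therefore does not show recruitment of macrophages. By at least 1.5-fold beyond counting error, 9 of the 28 immediate early, 4 of the 17 type I interferon and 2 of the 9 checkpoint genes were higher and 0 lower, and 4 of the 20 NF-kB and TNF genes were higher and 2 lower. By the same measure, 3 of the 6 recruited macrophage genes were higher and 2 lower, the class II genes H2-Aa at -0.81 and Cd74 at -0.74, and 1 of the 7 proliferation genes was higher. Interferon gamma and antigen presentation genes split 12 to 14 (median -0.07, percentile 18.1), with H2-Aa again and the chemokine Cxcl9 at 0.65.

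Vascular genes had 15 of 24 members higher (median 0.16, percentile 97.1), with the apelin receptor Aplnr at 1.97, Angpt1 at 1.39 and Sox18 at -1.69, and 6 were higher and 2 lower by at least 1.5-fold beyond counting error. Cytosolic ribosomal proteins had 26 of 34 higher (median 0.13, percentile 96.1), and matrix genes 19 of 27 (median 0.13, percentile 94.3), with Thbs1 at 0.90 and elastin, Eln, at -0.57, and 1 gene of each of these 2 lists was higher by that measure. The remaining lists had medians between -0.02 and 0.11: oxidative stress (-0.02, percentile 37.1, with Sod2 at -0.85), hypoxia (0.01, 50.2, with Vegfa at -0.83), the unfolded protein response (0.02, 55.1, with Atf3 at 0.58), phagocytosis and lysosome (0.04, 60.9), endothelial activation (0.05, 63.3), inflammasome and cell death (0.06, 72.4), complement (0.08, 73.3, with C4b at 0.87), p53 and senescence (0.09, 75.9) and resident macrophage genes (0.11, 80.3, with Pf4 at 0.71). Percentiles describe these 2 pools and carry no replicate check. Under a mitochondrial limit of 10% only 14 isotype and 7 PD1/PEM cells were left, and Myh6, Tnnt2 and Tpm1 then had log2 ratios of 0.03, 0.24 and 0.42, against -0.39, -0.39 and -0.43.

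**Figure D2:**
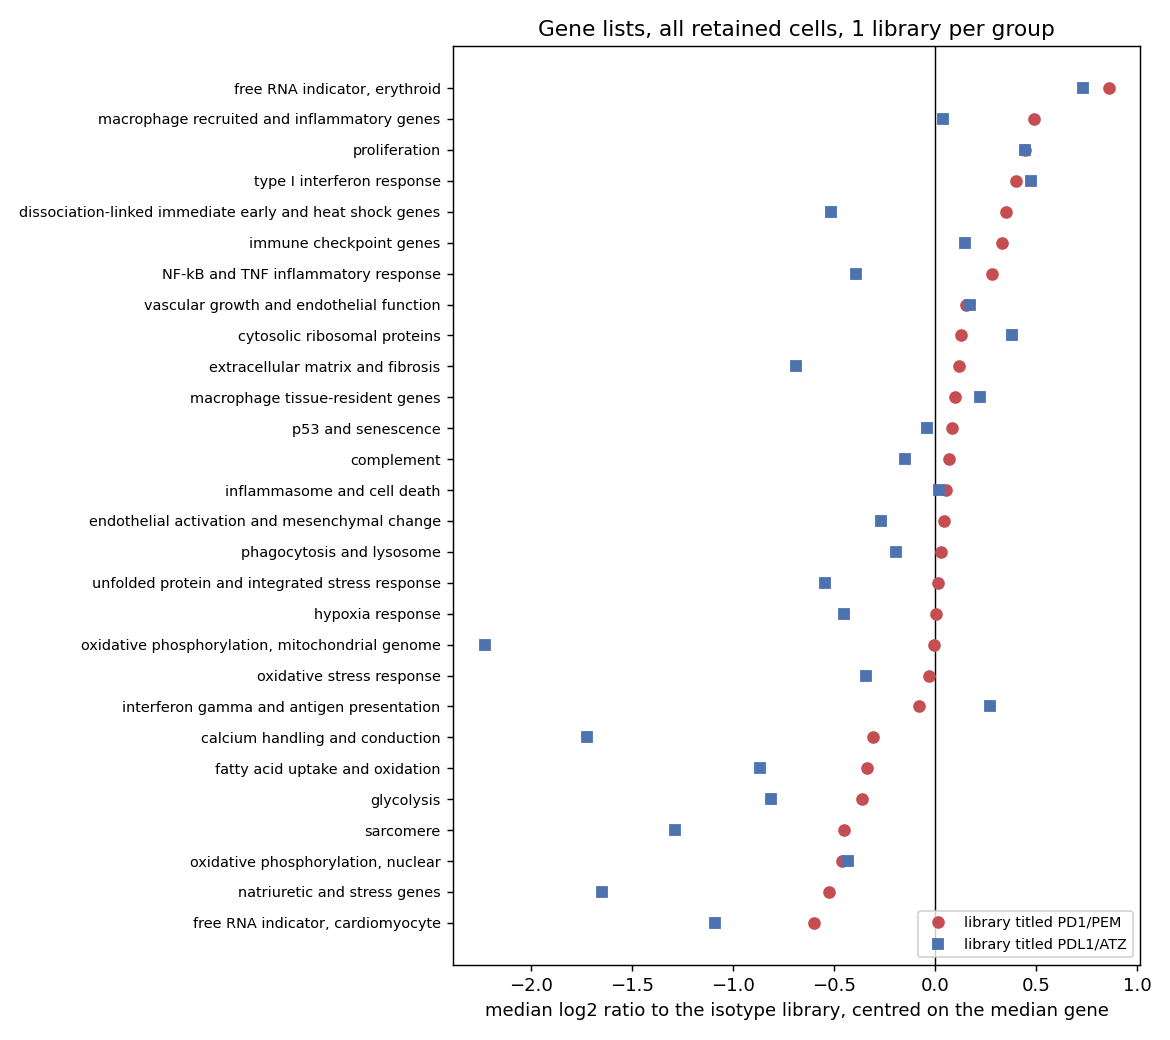
Median log2 ratio to the isotype library of each gene list over all retained cells, centred on the median gene, with 1 point per antibody library and no error bar because each group is 1 library. Sarcomere, natriuretic and fatty acid lists lie below 0 for both libraries, while the immediate early and NF-kB lists lie above 0 for PD1/PEM and below 0 for PDL1/ATZ, where without centring they were at 0.01 and 0.13.

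Within clusters the same directions were seen for several of these genes. In cluster 5, Klhl38 was 17.7-fold higher in PD1/PEM than in isotype cells (6.67 to 102), Egr3 4.39-fold, Fign 4.08-fold, Retreg1, a receptor for autophagy of the endoplasmic reticulum, 3.26-fold and Grb14 3.11-fold, while Bmp10 was 12.8-fold lower (4.76 to 74.3), Phka1 3.35-fold, Ptgds, a prostaglandin D synthase, 3.23-fold, Nppa 3.03-fold and Ppargc1a 2.49-fold. In cluster 6, Spry4 was 7.56-fold higher (3.33 to 26.4), the potassium channel Kcnb2 6.97-fold, Egr3 5.77-fold, the vessel growth factor Angpt1 4.18-fold and Slc24a2 3.87-fold, with Nppb 6.87-fold (4.79 to 10.4), Fhad1 6.36-fold, Flnc 4.95-fold, Bmp10 4.61-fold and the growth factor receptor Igf1r 3.06-fold lower. Sarcomere genes had medians of -0.64, -0.34 and -0.30 in clusters 3, 5 and 6, and immediate early genes of 0.35, 0.52 and 0.31. In cluster 3 the free cardiomyocyte RNA list, which shares most of its genes with the sarcomere list, was at -0.63 and the atrial list at -0.99. A change of sarcomere genes in these cells therefore cannot be told from a change in free RNA. The NF-kB and TNF list was at percentiles 97.6, 78.4 and 72.7. Genes at least 2-fold higher and lower numbered 79 and 86 of 8488 in cluster 3, 98 and 81 of 4982 in cluster 5, and 143 and 72 of 3982 in cluster 6. After thinning they were 38 and 36 in cluster 5 and 26 and 27 in cluster 6, and with at least 200 UMIs 22 and 19, and 30 and 19.

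In fibroblast-like cells Egr3 was 6.45-fold higher in the PD1/PEM library (2.82 to 22.6), Lrmda 3.25-fold, Dach1 3.20-fold, the antiproliferative gene Btg2 3.03-fold and Egr1 2.14-fold (1.76 to 2.63), and Mgp, which encodes matrix Gla protein, and the secreted protease gene Htra3 were 2.22-fold (1.83 to 2.70) and 2.66-fold lower, with Osbpl9 2.87-fold and Pcdh9 2.20-fold lower. Nppa, a transcript of cardiomyocytes, was 3.33-fold lower in these cells (2.71 to 4.13) and the free cardiomyocyte RNA list had a median of -0.46 there. The immediate early list as a whole had a median of 0.06 in this class, with 8 of 15 members higher, 5 of them and none of the lower ones by at least 1.5-fold beyond counting error. Of 698 genes 17 were at least 2-fold higher and 16 at least 2-fold lower, against 1 and 1 after thinning, 1 and 2 with at least 200 UMIs and 102 and 124 with at least 10. In macrophage-like cells, 6 against 11, Egr1 was 3.54-fold higher (1.81 to 8.94), Tcf4 3.08-fold, Flt1 2.58-fold, Timp3 2.18-fold and Zbtb16 2.18-fold, and the lowest genes were those of heart muscle: Nppa (4.38-fold), Tnnt2 (2.05-fold), Actc1 (2.02-fold), Myh6 (1.70-fold) and Ttn (1.56-fold). Mesothelial-like cells, 2 in each library, gave 2 such genes, Igfbp5, a binding protein of insulin-like growth factors (15.5-fold, 3.99 to 929), and Tmtc1 (3.38-fold).

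The PDL1/ATZ library was compared with the isotype library in the same way. Muscle genes and mitochondrial transcripts were lower: Ppargc1a stood at 50.5 against 2150 CPM (42.6-fold lower, 39.3 to 46.3), Bmp10 at 4.01 against 73.9 (18.3-fold, 13.6 to 25.4), mt-Nd6, a subunit of complex I encoded in the mitochondrial genome, at 115 against 1350 (11.7-fold) and Flnc at 32.7 against 374 (11.4-fold). Ryr3 (8.92-fold), the sarcomere genes Mypn (8.80-fold), Xirp1 (8.38-fold) and Myo18b (7.50-fold), Fam220a (11.9-fold) and the phosphatase Ptp4a1 (58.9-fold) were also among the lowest. The highest genes were nearly unread in the isotype library. Rnasek had 799 UMIs against 0 and was at least 84.8-fold higher, Tnfsf13 221 against 0 and at least 23.4-fold higher, both bounds set at 3 counts. Cpne1 (797 against 3 UMIs, ratio 72.5, 28.8 to 411), Mrpl53 (305 against 1, ratio 64.8, 17.3 to 3850), Adnp (55.9-fold), Atp6v0c (49.2-fold), Cox16 (35.9-fold), Schip1 (34.7-fold), Galnt2 (33.1-fold) and Pde2a (28.2-fold) followed. Over all deposited cells, before filtering, the isotype and PD1/PEM libraries held 2 and 2 UMIs of Rnasek, 3 and 0 of Tnfsf13 and 2 and 0 of Mrpl53, so these symbols were not left out as unread. Deposited isotype UMIs were also few for Cpne1 (11), Atp6v0c (20), Galnt2 (21), Adnp (37), Pde2a (70), Cox16 (90) and Schip1 (106). Those of PD1/PEM were few too, at 5, 30, 20, 26, 36, 91 and 71 in the same order. For 162 pairs of symbols of the same gene, 1 symbol was read in PDL1/ATZ only and the other in the other libraries only. The gene lists thus differed for those pairs. For all of the genes named here, a gene list that differs between libraries cannot be told from a difference of expression. The same holds for Ptp4a1 and Fam220a, with 22 and 31 UMIs over all deposited PDL1/ATZ cells against 1354 and 535 of the isotype library. Both symbols, and Atp5o, have 2 overlapping entries in the annotation, so their counts are uncertain.

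The median of all genes lay 0.52 above 0 on the log2 scale for PDL1/ATZ against isotype, and the values of lists and their members that follow are relative to it. Of 13766 genes 3137 were at least 2-fold higher and 477 lower, so that 86.8% of them were higher. Centred on the median gene the numbers were 1015 and 1128, with 47.4% higher. Genes higher were 1971 with totals that left out mitochondrial, haemoglobin and ribosomal genes and 1769 with at least 200 UMIs. Over all retained cells both interferon lists lay above the median gene: type I interferon response genes with 20 of 21 members (median 0.47, percentile 99.8), led by Oas1a at 1.86 and Isg15 at 1.61, and interferon gamma and antigen presentation genes with 20 of 27 (median 0.27, percentile 98.9), led by the immunoproteasome subunits Psmb9 at 1.23 and Psmb8 at 1.04. Ribosomal protein genes had 32 of 34 members higher (median 0.38, percentile 100), with Rpl13a at 3.81. Rpl13a stood at 26.7 CPM in isotype, 33.4 in PD1/PEM and 541 in PDL1/ATZ, far from the rest of its list. For Rpl13a too, a gene list that differs between libraries cannot be told from a difference of expression. Vascular genes had 19 of 25 higher (median 0.18, percentile 96.5), with Aplnr at 3.23, the tip cell gene Esm1 at 1.66 and the chemokine Cxcl12 at 1.46. Resident macrophage genes had 10 of 13 higher (median 0.22, percentile 92.7), with Pf4 at 1.59, and proliferation genes 9 of 14 (median 0.45, percentile 93.5).

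Muscle and metabolic lists lay below the median gene in the PDL1/ATZ library. The 13 genes of the mitochondrial genome had a median of -2.23, calcium handling genes -1.72 (all 15 lower, with the release channel Ryr2 at -3.21), natriuretic and stress genes -1.65 (all 9 lower, with Nppb at -3.33) and sarcomere genes -1.29 (all 20 lower, with titin, Ttn, at -2.76). Medians were -0.86 for fatty acid genes (25 of 30 lower, with Pdk4 at -2.95 and Cpt1b, with 14 deposited isotype UMIs, at 4.5), -0.81 for glycolysis (17 of 20 lower), -0.69 for matrix genes (27 of 28 lower, with Thbs1 at -2.02 and Col1a1 at -1.70) and -0.43 for nuclear oxidative phosphorylation (45 of 50 lower, percentile 1.6, with Atp5o at 3.08). Without centring the last of these turned, with 28 of 50 members higher and a median of 0.09. The percentile was 0.0 for each of the other lists named so far in this group. The free cardiomyocyte RNA list, most of whose genes are also sarcomere genes, had a median of -1.09 (percentile 1.2). The 4 haemoglobin genes had a median of 0.73, with Hba-a2 at -2.88. Hba-a2 stood at 53.4 CPM against 273 in isotype, while Hba-a1 stood at 3890 against 1500. For Hba-a2 a gene list that differs between libraries cannot be told from a difference of expression.

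Stress lists also lay below the median gene: the unfolded protein response (-0.55, percentile 0.3, with the chaperone Hspa5 at -1.65), immediate early and heat shock genes (-0.51, percentile 1.1, with Hsph1 at -1.77), hypoxia (-0.45, percentile 1.7, with Vegfa at -2.81) and NF-kB and TNF genes (-0.39, percentile 0.5, although Il1b was at 1.30). Without centring the hypoxia, immediate early and NF-kB medians were 0.07, 0.01 and 0.13. The other lists were at -0.34 for oxidative stress (percentile 6.2), -0.27 for endothelial activation (17.4), -0.19 for phagocytosis and lysosome (37.1), -0.15 for complement (30), -0.04 for p53 and senescence (56.2), 0.02 for inflammasome and cell death (55.0), 0.04 for recruited macrophage genes (58.8) and 0.15 for immune checkpoint genes (69.3). Of these, oxidative stress, endothelial activation, phagocytosis, complement and p53 genes were above 0 without centring, at 0.18, 0.26, 0.33, 0.37 and 0.48. The mitochondrial share, the barcodes and the gene symbols of this library differed from those of both others. With 1 library per group, an effect of the antibody on expression cannot be told apart from what came with these differences. Under the mitochondrial limit of 10%, which left 14 isotype and 8282 PDL1/ATZ cells, the genes at least 2-fold higher numbered 119.

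These values over all cells compare libraries that occupied different clusters, and several lists lay elsewhere within clusters 3, 5 and 6, which held 47, 64 and 40 PDL1/ATZ cells. Relative to the median gene of each cluster, interferon gamma genes were at 0.07, -0.24 and 0.13 in the same order (percentiles 51.6, 24.2 and 48.3), and at -0.22 in fibroblast-like cells (22.7). Type I interferon genes reached 5 measured members in cluster 3 alone, where 6 of 8 were higher (median 0.66, percentile 95). Ribosomal protein genes were at 0.47, 0.26 and 0.08 (percentiles 100, 90.2 and 30.2), and in fibroblast-like cells 27 of 34 were lower (median -0.31, percentile 6.2). Vascular genes were at 0.09, 0.05 and -0.18 (percentiles 57.4, 55.0 and 20.5), and at 0.39 in fibroblast-like cells (96.4). Without centring, interferon gamma and ribosomal protein genes were at 0.11 and 0.02 in fibroblast-like cells and vascular genes at 0.01 in cluster 6.

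Calcium handling genes were at -0.23, -0.26 and -0.49 in clusters 3, 5 and 6 (percentiles 14.1, 12.8 and 4.2), short of the -1.72 over all cells, and without centring 8 of 14 were higher in cluster 3 (median 0.08). In fibroblast-like cells they were at -1.48. Sarcomere genes were at -0.48 in clusters 3 and 5 (percentiles 0.7 and 1.3), with 17 of 20 lower in cluster 6 (percentile 2.2), and at -1.26 in fibroblast-like cells. Beside them, all 10 transcripts taken as a sign of free cardiomyocyte RNA lay below the median gene in fibroblast-like cells (median -1.25), and this list was at -0.43, -0.48 and -1.01 in clusters 3, 5 and 6. Most of these 10 transcripts are also in the sarcomere list, so the 2 lists are not independent. The hypoxia list was at 0.22 in cluster 3 (percentile 69.8), and the NF-kB and TNF list at -0.36 there (percentile 8.6) and at -0.06 in fibroblast-like cells (percentile 40.6, and 0.27 without centring). Genes of the mitochondrial genome (-1.66, -1.91 and -2.24), natriuretic and stress genes (-1.13, -0.98 and -1.32), matrix genes (-1.02, -1.04 and -0.92) and immediate early genes (-0.80, -0.62 and -0.77) lay below the median gene in all 3 clusters.

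Within classes, mitochondrially encoded genes made up most of the genes ranked lowest in the PDL1/ATZ library. The ranking is by the interval bound nearest no difference, not by fold. In fibroblast-like cells mt-Nd3 was 6.04-fold lower (5.53 to 6.58), mt-Nd4l 6.49-fold, mt-Atp8 5.71-fold and mt-Nd2 4.48-fold, together with Thbs1, a matrix glycoprotein (8.62-fold, 5.42 to 13.9). Gse1 (at least 13.3-fold) and Schip1 (at least 5.71-fold), both with 0 isotype UMIs there, Rpl13a (18.9-fold), Stard13 (17.9-fold) and the interferon-inducible Ifi203 (15.9-fold) were highest. The limit on gene lists given above for Schip1 and Rpl13a holds here too. In macrophage-like cells mt-Nd4l was 7.20-fold, mt-Nd3 6.0-fold, mt-Nd2 4.27-fold and mt-Atp6 4.15-fold lower and Ttn was also among the lowest, beside a median of -1.5 for free cardiomyocyte RNA, with Rbpj, the Notch pathway transcription factor, 11.1-fold higher (4.41 to 62.9), Dach1 7.95-fold, Fli1 6.98-fold, Mgll 5.25-fold and Stox2 at least 2.96-fold. Mesothelial-like cells had mt-Nd5 8.44-fold, mt-Nd3 7.23-fold, mt-Nd2 5.28-fold, mt-Nd4 5.17-fold and mt-Atp6 4.64-fold lower, and Airn (5.65-fold), Plxna4 (5.41-fold), Rbfox1 (4.27-fold), Mast4 (3.33-fold) and Tshz2 (at least 1.87-fold) highest. The median gene lay 0.33, 0.33 and 0.11 above 0 in these 3 classes. Genes at least 2-fold higher and lower numbered 540 and 183 in fibroblast-like cells (74.7% higher, and 46.5% once centred), 92 and 48 in macrophage-like cells (65.7% and 40%) and 11 and 31 in mesothelial-like cells (26.2% and 19.5%).

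The antibody libraries were also compared directly, PDL1/ATZ against PD1/PEM. Immediate early and mitochondrial genes were lower in the PDL1/ATZ library: all 28 immediate early and heat shock genes lay below the median gene (median -1.05, percentile 0.0; without centring 22 of 28 were lower, with a median of -0.54), as did the 13 genes of the mitochondrial genome (median -2.11). Interferon gamma genes lay above it with 21 of 27 members (median 0.33, percentile 99.9) and type I interferon genes with 14 of 21 (median 0.29, percentile 96.8). Within clusters 3, 5 and 6 interferon gamma genes were at percentiles 68.9, 38.1 and 54.6. Over all retained cells 21 of 24 NF-kB and TNF genes lay below the median gene (median -0.60, percentile 0.0, and -0.085 without centring). The NF-kB and TNF list was at percentile 9.5 in cluster 3 and, with a median of 0.09, at 39.7 in fibroblast-like cells. Ptp4a1 (52.8-fold), Ppargc1a (17.4-fold), mt-Nd6 (12.4-fold), the fibroblast growth factor homologous factors Fgf12 (7.62-fold) and Fgf13 (5.86-fold), and Chrm2, the muscarinic receptor of the heart (5.77-fold), were among the genes lowest in the PDL1/ATZ library. Rnasek (at least 87.6-fold), Mrpl53 (at least 33.5-fold) and Nudt8 (at least 24.6-fold) had 0 UMIs in the PD1/PEM library and were among the highest, with Adnp (50.1-fold) and Umad1 (40.5-fold), and the limit on rarely read symbols holds for these 5 and for Ptp4a1 too. Of 13772 genes 2775 were at least 2-fold higher and 439 lower (86.3% higher), and 842 and 1016 (45.3% higher) once centred on a median gene at 0.51. Under the 10% limit they were 20 and 209, with at least 200 UMIs 1419 were higher, and without a mitochondrial limit 292 were lower.

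Cd274 (chromosome 19, 29367455 to 29388095), which encodes PD-L1, had 42 UMIs in the isotype, 38 in the PD1/PEM and 215 in the PDL1/ATZ library, or 10.6 (7.63 to 14.3), 9.27 (6.56 to 12.7) and 17.3 (15 to 19.7) CPM. Its log2 ratio to isotype was -0.19 for PD1/PEM, within counting error, and 0.69 for PDL1/ATZ, or 0.17 relative to the median gene. Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes PD-1, had 0, 1 and 14 UMIs, and the 0 of the isotype library allows up to 0.757 CPM. Levels this low do not allow a fold for PD1/PEM. Of the sex-linked genes, Xist, the RNA of the inactive X chromosome, had 1, 2 and 3 UMIs and the Y-linked Ddx3y 426, 499 and 1914. Uty was at 106, 119 and 173 CPM, Eif2s3y at 39.3, 43.4 and 53.9, and Kdm5d at 22.2, 14.6 and 26.0, with Tsix at 1.01, 0.244 and 2.17. Relative to the median gene Ddx3y and Eif2s3y were at -0.01 and -0.07 in the PDL1/ATZ library, and under the 10% limit the log2 ratio of Ddx3y was -1.03.

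Whether the antibody libraries departed from isotype along the same genes was described by the correlation of their log2 ratios across 10431 genes, which are not independent replicates. Pearson r was 0.419 and Spearman rho 0.425, with a covariance of 0.120. Both ratios share the isotype library: Poisson draws with no difference between libraries gave a mean r of 0.619 and a covariance of 0.0257, over a mean of 11024 genes that reached 50 UMIs in the draws. With the isotype cells split at random, so that each ratio had its own part, r was 0.305, rho 0.298 and the covariance 0.0935 over a mean of 9510 genes. Among genes with at least 200 UMIs the split gave an r of 0.422 over 4457 genes, against 0.465 over 5477 without it. Splitting the cells of 1 library removes shared counting error and leaves whatever else is particular to that library, so part of the covariance may still come from the shared isotype hearts.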

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

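The tests of barcodes, gene symbols, atrial genes, the sarcomere list and scaling were chosen after the results were seen, while those of gene span and of the list within clusters were set beforehand. The medians of 2 gene lists were on opposite sides of the median gene in the antibody libraries, by a rule of at least 0.25 on each side that was set after the data were seen, and neither difference was tested. The NF-kB and TNF response list was at 0.28 in the PD1/PEM and -0.39 in the PDL1/ATZ library, a difference of -0.67. Within classes it was at -0.36 in cluster 3 and -0.06 in fibroblast-like cells of PDL1/ATZ, at percentiles 8.6 and 40.6. The immediate early and heat shock list was at 0.35 and -0.51, a difference of -0.86. Without centring the PDL1/ATZ medians of the NF-kB and immediate early lists were 0.13 and 0.01, so the opposite sides rest on centring.

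Scaling, in which other transcripts take fewer UMIs, is argued against for the higher immediate early genes of the PD1/PEM library, since it would raise all genes alike, whereas the median of all 10620 genes was 0.007 against 0.356 for the list. A handling difference of the whole pool, such as digestion time, would raise the list in every cluster, and the medians were all above 0, at 0.351, 0.523 and 0.311 in clusters 3, 5 and 6, 0.597 for the 4 measured members in cluster 1 (43 isotype and 59 PD1/PEM cells) and 0.06 in fibroblast-like cells. In that class 8 of 15 members were higher and 7 lower, but 5 and 0 of them by at least 1.5-fold beyond counting error. The medians thus met what was predicted for handling, but a requirement that members go the same way, added after the values were seen, was not met. An effect of the antibody on the whole tissue would also raise the list in every cluster. These medians therefore cannot tell handling from the antibody, and both are left open. The antibody was not tested, because each group is 1 pool.

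The lower Nppa and Nppb of the PD1/PEM library were weighed in the same way. A uniform drop of cardiomyocyte transcripts would put Nppa near the sarcomere genes. Nppa lay -1.18 from the median of the sarcomere list, whose members had an SD of 0.226. It was picked because it was low, and the rule was set afterwards. The distance therefore describes Nppa alone and is no test of a uniform drop for other genes. Less atrial tissue in the PD1/PEM pool stays open as an explanation. Bmp10 was at -2.91, Sln at -1.0, Myl7 at -0.85 and Myl4 at -0.67, but Bmp10 was among the genes that prompted the atrial list. The ventricular gene Myl3 lay as low as Myl7, at -0.84. The ventricular median of -0.52 was nonetheless above the atrial one of -0.93. The atrial median lay -0.479 from the sarcomere median, short of the -0.59 that had been required. Myl7 and Myl4 are in both of these lists. Atrial content and the antibody therefore cannot be told apart, with 1 pool per group.

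The PDL1/ATZ library stood apart from both others in technical measures. It shared 0 barcodes with the isotype library, where the overlap of the other pair would give 41.8, and 161 symbols with at least 500 UMIs in 1 of these 2 libraries had 0 in the other, against 0 for the other pair. Both values are consistent with another barcode set and another gene list for this library. For 162 pairs of symbols of the same gene, 1 symbol was read in PDL1/ATZ only and the other in the other libraries only. The gene lists thus differed for those pairs. The 3 matrices were deposited with 1 list of symbols, so a gene list of its own would have to have been merged with the other before deposit, which was not tested. More nuclear or intronic RNA stays open, with a Spearman rho of 0.062 across genes between gene span and the ratio to isotype, below the 0.184 of PD1/PEM and above the -0.004 of PDL1/ATZ against PD1/PEM. The antibody was not tested apart from these, since the same library carries all of them.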

How the results depend on the processing

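Of the settings tried, those that kept every deposited cell, kept the symbols read in only 1 set of libraries, named clusters with tied markers, clustered the isotype and PD1/PEM libraries together with no mitochondrial limit, or used all cells and numbered clusters were added after the data were seen. No paired analysis was possible because each group is 1 library. Of the list medians 199 were close to their main value, 112 moved and 16 reversed, and of the ratios of named genes 1456 were close, 426 moved and 12 reversed. No ratio was computed for named genes brought to 3 or fewer UMIs by a setting, a rule added after results were seen (90 genes under the 10% mitochondrial limit and 6 under thinning, all PDL1/ATZ against isotype). Ratios were recomputed against isotype only. Depth limits the named classes, with 6 isotype macrophage-like and 2 mesothelial-like cells. Over all retained cells, Nppa, Nppb and Bmp10 stayed lower and Egr1 and Egr3 higher in PD1/PEM than in isotype under each cell filter, scaling and thinning run for them. The cause was not tested where none is given.

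Fibroblast-like shares were 1.12% in the isotype and 1.05% in the PD1/PEM library at resolution 0.5. Without doublet removal the PDL1/ATZ shares were 3.68% fibroblast-like, 1.68% macrophage-like and 1.29% mesothelial-like. Macrophage-like and mesothelial-like shares of the isotype and PD1/PEM libraries were 0% under the 10% limit, with few cells left. They were also 0% when each library was clustered alone, because no cluster of these libraries met the marker rule. Fibroblast-like cells could not be named under the 10% limit, without a mitochondrial limit, with at least 500 genes, at resolution 2, with each library clustered alone, or with the isotype and PD1/PEM libraries clustered together and no mitochondrial limit, a setting that alters 2 choices at once and under which mesothelial-like cells could not be named either.

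For PD1/PEM against isotype over all retained cells, genes at least 2-fold higher and lower numbered 1 and 3 under the 10% limit, 261 and 185 with at least 10 UMIs and 45 and 26 with at least 200. In fibroblast-like cells they numbered 1 and 1 after thinning, 102 and 124 with 10 UMIs and 1 and 2 with 200. In cluster 5 they numbered 38 and 36 after thinning, 276 and 234 with 10 UMIs and 22 and 19 with 200, and in cluster 6 26 and 27, 355 and 210, and 30 and 19. Other minimums test more or fewer genes, and thinning leaves fewer UMIs. For PDL1/ATZ against isotype, genes higher numbered 119 under the 10% limit, 1015 centred, 1971 with totals without mitochondrial, haemoglobin and ribosomal genes and 1769 with 200 UMIs, and genes lower 1128 centred. For PDL1/ATZ against PD1/PEM, genes higher numbered 20, 842, 1658 and 1419 under the same 4 settings, and genes lower 209 under the 10% limit, 292 without a limit, 285 with every deposited cell and 1016 centred.

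Under the 10% limit, with 14 isotype and 7 PD1/PEM cells, log2 ratios reversed for Myh6 (0.03), Tnnt2 (0.24) and Tpm1 (0.42) in PD1/PEM, and for Myl3 (0.81), Ddx3y (-1.03), Myl2 (1.40), Mb (0.32) and Fabp3 (0.67) in PDL1/ATZ against isotype. Tnfsf13 (-0.96) and Mrpl53 (-0.62) also fell below 0 there, but had 0 and 1 isotype UMIs even before this limit, so their sign comes from the pseudocount over a small total. A wider form of the rule on 3 UMIs, which would have left out both, was tried after these values were seen and not kept. Centring gave Ddx3y -0.01 and Eif2s3y -0.07. List medians of PDL1/ATZ against isotype reversed when centred and with the reduced totals for NF-kB and TNF (-0.39, -0.08), nuclear oxidative phosphorylation (-0.43, -0.12), hypoxia (-0.45, -0.14) and immediate early genes (-0.51, -0.20, and -0.01 as a mean over cells). Against PD1/PEM they reversed for the unfolded protein response (-0.48, -0.19 and -0.09 under the same 3 settings), p53 and senescence (-0.43, -0.14, -0.02) and glycolysis (0.01 as a mean over cells). The correlation across genes was 0.305 with split isotype cells.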

Other observations

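The lists and genes here were chosen after the data were seen. Of 5 measured ventricular genes 4 were lower in the PD1/PEM than in the isotype library (median log2 ratio -0.52, percentile 0.5), 2 of them by over 1.5-fold beyond counting error, with Myl3 at -0.84, Myl2 at -0.59, Myh7 at -0.52 and Lbh at -0.22, while Rasl11b was at 0.08 (-0.43 to 0.58). Myl3, Myl2 and Myh7 are also in the sarcomere list. The atrial list, with all 4 members lower, had a median of -0.93. In the PDL1/ATZ library, relative to the median gene, the atrial list was at -0.72 and the ventricular list at -1.06.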
